A study of Homo sapiens with 5 samples.

How the data were processed

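RNA was measured on 5 Illumina human expression bead arrays: 2 of vehicle-treated (DMSO) cells and 3 of cells given 1 µM K-11706 for 48 h. Per the labels' protocols, total RNA was taken up in Trizol, cleaned on silica columns, amplified and biotin-labelled before hybridisation. Groups came from the treatment label of each sample and replicate numbers from its title (1 and 3 for DMSO, 1, 2 and 3 for K-11706). The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The treatment protocol attached to both DMSO samples describes another compound, bufalin, or its control, while their treatment label reads DMSO; they were used as the vehicle group that the series' design text names.

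The deposited scanner table gives, per the file headers, a signal intensity that is not normalized and a detection p-value for each probe on each array. It has 47422 lines for 47323 different probes; 99 probe IDs were listed again with identical signals and were used once. A second deposited table holds the authors' processed values of 21534 probes on a log2 scale. The submitters' processing notes name lumi, with no version; the background correction, transformation and normalization behind that table are not given in the sources used here. Set against the scanner signals, the authors' log2 values follow the same arrays in the same direction: across probes, which are not independent, the deviations from each probe's mean correlated at 0.988 to 0.993 with those of the same array's log2 signals. The medians of the 5 arrays lay between 7.778 and 7.779 in the authors' table, which is therefore not centred on 0. It holds every probe with a detection p-value under 0.01 on at least 1 array (19669 probes) and 1865 others, by a rule not given in the sources used here.

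Scanner intensities were corrected for background with the normexp model of limma 3.58.1 in R 4.3.3. The negative control distribution was inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized and put on a log2 scale. The offset draws fold changes of dim probes towards 1. A probe was tested when its detection p-value was under 0.05 on at least 2 arrays, which left 20344 probes. Each was fitted with lmFit and moderated with eBayes (3 residual and 4.05 prior degrees of freedom), the 2-sided p-values were adjusted by the Benjamini-Hochberg method over all tested probes, and an adjusted p-value under 0.05 was called a change. Every log2 fold change is K-11706 minus DMSO.

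Gene names came from GEO's platform annotation of the probes in the authors' table. It names 15827 probes by 1 symbol and 4 by several, and leaves 5703 of the authors' probes unnamed here; 15816 of its probes matched the RefSeq gene table by gene ID, which changed no symbol. Of the tested probes, 14663 carried 1 symbol and stood for 11077 genes, and 5681 had no single name and entered only the probe counts. A gene was represented by its tested probe with the highest mean signal. Among 2897 genes with several tested probes, 20 had probes past the threshold in opposite directions. A gene detected on every array of one group and on no array of the other has only a bound: its fold is given as at least the ratio of the bright group's mean to the dim group's mean, where each dim array takes the higher of the probe's own value and the lowest detected signal on that array. Such a bound holds only for values processed in this way: without background correction, with an offset of 50 and in the authors' values the folds of the named genes with a bound were smaller.

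Before the data were examined, 33 gene lists, 12 focus genes (some not reported here), the rule for named genes and the alternatives were fixed. The 30 lists with at least 5 tested members were compared with all other genes by camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30; camera with a correlation estimated per list and fry were run beside it. The rule names the focus genes; the 12 largest rises and 12 largest falls among called genes detected on all arrays with no overlap between groups; the 3 largest bounds per direction; and up to 4 members with the smallest p-value of each called list and of the androgen-induced list. Other genes are named where a count was small or a group was noticed, and are said to have been chosen after their values were seen.

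The same steps were tested on simulated data built from the background and mean signals of these arrays and the spread of their brighter probes, with 200 of the probes changed. Of 20383 simulated probes tested for K-11706 against DMSO, 70 were called and 3 of these were unchanged. None of 66 probes changed 1.5-fold, 15 of 66 changed 2-fold and 52 of 66 changed 4-fold were recovered. Far fewer probes changed in the simulation than were called in the data (6747). This makes the adjusted threshold stricter in the simulation, so these shares do not give the recovery in the data. The median fitted log2 change was 0.926, 0.830 and 0.895 of the simulated one, in that order. For a list of 40 independently simulated probes shifted by 1 on the log2 scale, camera with an estimated correlation gave p = 0.000216. With the preset correlation camera gave p = 1.31e-74 for the same list, so the estimate weakens a call even where probes are independent. The number of arrays limits the precision of every value.

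The alternatives were no background correction, an offset of 50, scaling to the 75th percentile in place of quantile normalization, the authors' values, no filter, detection on all 5 arrays at p under 0.01, an intensity trend with robust moderation, array weights, the replicate number as a block, each array left out in turn, the mean of a gene's probes, the 2 other list tests, and a minimum fold of 1.2 (treat). Changes to the members of 3 lists and of 4 gene families were added after the data were seen. The tables name no slide, so a slide block was not run. Plots were drawn with matplotlib 3.10.9.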

Results

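Gene expression was measured in an enzalutamide-resistant derivative of LNCaP, an androgen-responsive human prostate cancer cell line. Resistance had been selected in 25 µM enzalutamide, an antiandrogen drug, and the cells were then maintained in 10 µM. Cells received vehicle (DMSO, 2 arrays) or 1 µM K-11706 (3 arrays) for 48 h. Of 47323 probes, 19120 and 19251 were detected on the DMSO arrays and 19097, 19363 and 18924 on the K-11706 arrays. Across the tested probes, which are not independent, normalized log2 signals correlated at 0.992 between the DMSO arrays, at 0.988 to 0.991 among the K-11706 arrays and at 0.948 to 0.951 between groups.

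The single comparison of the design asks which transcripts differ after exposure to K-11706, a compound that the series title ties to GATA2 in prostate cancer. Genes of the cell division cycle fell most broadly: all 51 measured G2/M genes and 36 of 37 S-phase genes were lower in the treated cells. Also lower were 9 of 12 androgen-repressed genes, 24 of 32 amino acid and stress response genes controlled by ATF4, 18 of 26 MYC and ribosome biogenesis genes and 11 of 23 endoplasmic reticulum chaperones, while 24 of 38 lysosome and autophagy genes rose. Camera called these lists with its preset correlation and none of them with an estimated correlation (adjusted p = 0.0674 to 0.100 with an estimated correlation). The estimates for these lists ran from -0.0782 (androgen-repressed genes) to 0.0394 (ATF4 genes), on both sides of the preset 0.01. A higher correlation among members therefore does not account for every lost call. For a simulated list of independent probes the camera p also rose, from 1.31e-74 to 0.000216, with an estimated correlation. A lost call can therefore reflect the test as well as the list. GATA2 itself rose 2.12-fold, and its log2 signal was 9.01 ± 0.33 (SD, n = 2) in DMSO and 10.09 ± 0.26 (SD, n = 3) with K-11706.

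In all, 3537 probes rose and 3210 fell among 20344 tested (limma, adjusted p-value under 0.05), of which 818 and 1119 changed at least 2-fold. With 1 probe per gene, 2274 genes rose and 1922 fell among 11077. The groups did not overlap for 57.9% of probes, where chance gives 20%. Fold sizes depended on the processing: 44 of 139 called genes named in the text had folds over 1.5 times smaller in the authors' values and 36 without background correction, and none had folds over 1.5 times larger under either. Some histone genes named near the end are not among the 139. The counts rest on both DMSO arrays: without DMSO replicate 1, 1488 probes rose and 1642 fell, and without DMSO replicate 3, 1729 rose and 1724 fell. No label or table names a batch that holds both groups, so a batch difference and the treatment cannot be told apart.

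GATA2, a zinc finger transcription factor, had a log2 fold change of 1.08 (SE 0.21, adjusted p = 0.00837) and was higher on 3 of 3 treated arrays than on either DMSO array. Without DMSO replicate 3 the change was 0.85 with an adjusted p of 0.0646, the highest of its alternatives, which ran down to 0.000122. FOXM1, a transcription factor that drives G2/M genes, fell 9.35-fold (log2 fold change -3.23, SE 0.14, adjusted p = 2.06e-05), or 3.28-fold in the authors' values, and its second probe fell 5.16-fold. TMPRSS2, an androgen-induced serine protease, rose 4.69-fold (log2 fold change 2.23, SE 0.17, adjusted p = 0.000214). The pioneer factor FOXA1 (0.35, SE 0.14, adjusted p = 0.105) and the co-chaperone FKBP5 (-0.35, SE 0.14, adjusted p = 0.0965) did not pass the threshold, but both did under 4 alternatives. KLK2 was detected on 1 of 5 arrays and was not tested. KLK3, IGF2, POM121 and EPO were not analysed here.

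Among 11 measured genes tied to GATA2 in prostate cancer, 8 were lower and 3 were not called (8 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.12. Camera called the list lower (adjusted p = 2.01e-05; adjusted p = 0.0736 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell 36.7-fold, AURKA, a mitotic kinase, fell 14.7-fold (14.9-fold and 6.55-fold in the authors' values), and MYC fell 2.17-fold. E2F1 (-0.23), CCND1 (-0.06) and PAK4 (0.45), named after their values were seen, were not called, PAK4 being the 1 higher gene of the list alone and passing the threshold under 5 alternatives (adjusted p over its alternatives 0.0112 to 0.382). The list shares members with the cell cycle lists: without those, in a test added after the data were seen, 4 of 7 genes were lower with a median log2 fold change of -0.41, and camera made no call (adjusted p = 0.0596). These 4 were FOXM1, MYC and, named after their values were seen, GNPNAT1 and KPNB1, of which GNPNAT1 (without DMSO replicate 3, 0.0599) and KPNB1 (without DMSO replicate 1, 0.171) lost their calls at the adjusted p-values given, the highest of their alternatives, 2 and 6 of which ended the call. Of 11 measured genes in the list of GATA2 and partner factors, 3 rose and 1 fell, the same counts adjusted over the list alone, and camera made no call (adjusted p = 0.496). The risers were GATA2, the coactivator NCOA1 and GRHL2, and the histone demethylase KDM1A fell, 3 of these named after their values were seen. The calls of GRHL2 (0.0655 without DMSO replicate 3), NCOA1 (0.0553 without DMSO replicate 1) and KDM1A (0.115 without DMSO replicate 1, and under 3 others) were lost at these adjusted p-values, the highest of their alternatives.

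Of 27 measured androgen-induced genes, 9 rose and 2 fell, also when adjusted over the list alone, and camera made no call (adjusted p = 0.372; median log2 fold change 0.17), nor without CENPN in a test added after the data were seen (adjusted p = 0.200). Fry, which tests a list on its own, called the full list higher (fry adjusted p = 0.00189). Besides TMPRSS2, LIFR, a cytokine receptor, rose 2.59-fold (1.39-fold in the authors' values). SPDEF, a luminal transcription factor, fell 3.75-fold, and CENPN, a centromere protein, fell 4.65-fold. Of 12 measured androgen-repressed genes, 9 fell and none rose (10 lower adjusted over the list alone), with a median log2 fold change of -2.89 (camera adjusted p = 6.39e-07; adjusted p = 0.0674 with an estimated correlation). The UGT2B genes, which encode glucuronidating enzymes, among them UGT2B15 and UGT2B17 that act on androgens, led this list: UGT2B10 fell 43.8-fold, UGT2B11 39.7-fold, UGT2B15 37.8-fold and UGT2B17 30.5-fold, and UGT2B28 was undetected on the treated arrays and at least 54.7-fold lower. These sizes hold for the processing used: in the authors' values the 5 folds were 9.84, 19.0, 9.84, 15.3 and 10.9 in the same order, and a second probe of UGT2B15, detected on 1 of 3 treated arrays, fell 15.8-fold. UGT2B17 read 11.81 on both DMSO arrays and 6.87 ± 0.23 (SD, n = 3) with K-11706. These UGT2B genes are related in sequence, to a degree that was not compared here. Without them, in a test added after the data were seen, 4 of 7 members were lower (adjusted p = 0.0332; adjusted p = 0.278 with an estimated correlation), and with UGT2B17 standing for all 5, also added then, 5 of 8 were lower (adjusted p = 0.00398; adjusted p = 0.161 with an estimated correlation). The 4, named after their values were seen, were CAMK2N1, which fell by 3.58 on the log2 scale, DDC, which fell by 2.19, BCHE, which fell by 0.89 (-0.22 in the authors' values), and PEG3, which was detected on 1 of 3 treated arrays, fell by 0.70 and lost its call without DMSO replicate 3, without background correction and in the authors' values (adjusted p = 0.0871, the highest of its alternatives), where its log2 fold change was -0.15. OPRK1 (-0.42), ACKR3 (0.28) and MET (0.50) were not called. ACKR3 passed the threshold, upwards, under 3 alternatives (adjusted p 0.0103 to 0.398 over its alternatives) and OPRK1, downwards, under 2 (0.0312 to 0.308).

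**Figure D1:**
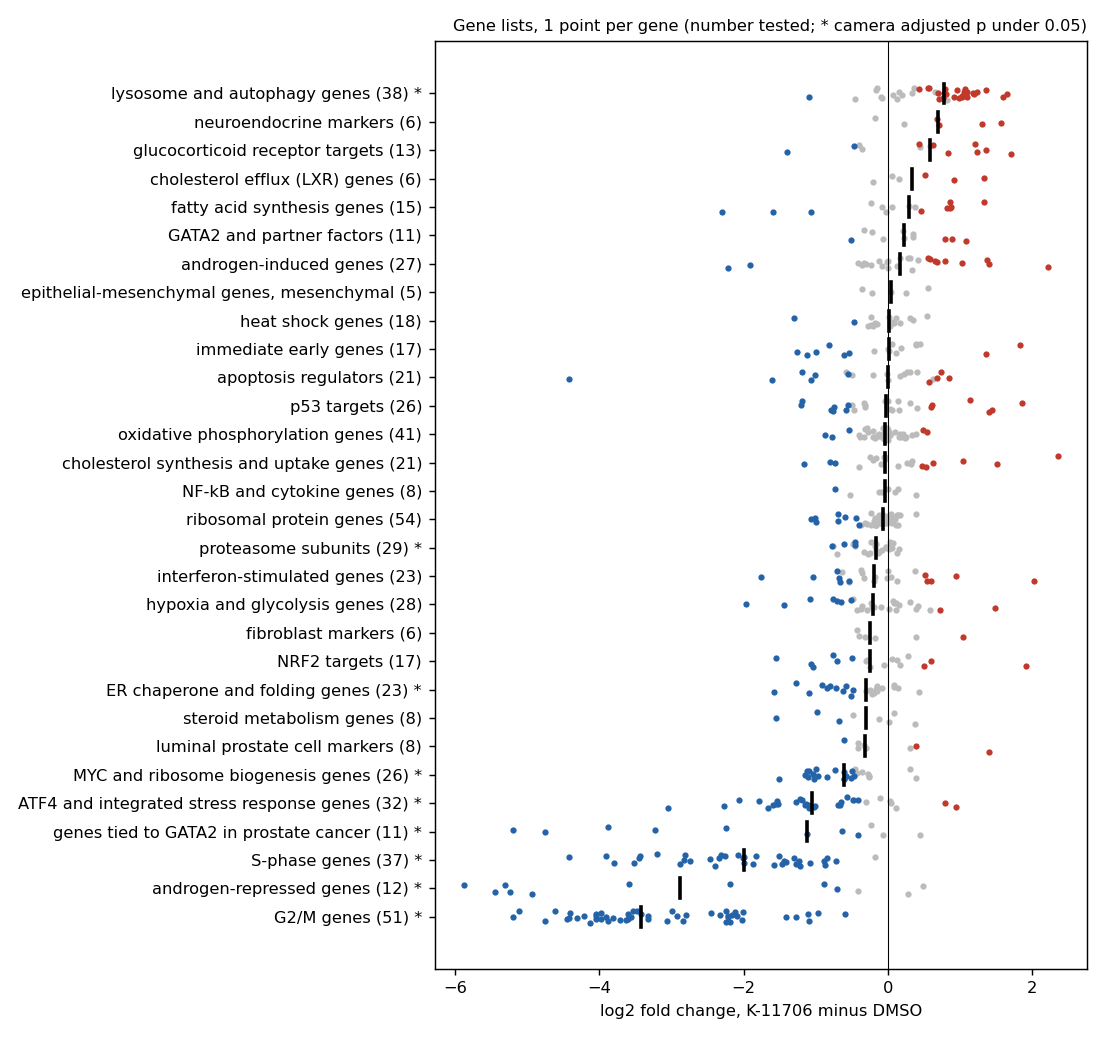
Each point is the log2 fold change (K-11706 minus DMSO, horizontal axis) of 1 gene, with gene lists on the vertical axis sorted by median (black bar) and the number of tested genes in brackets. Red points rose, blue points fell and grey points were not called (limma adjusted p-value under 0.05), and an asterisk marks a camera call; the G2/M median lies at -3.42 and the lysosome and autophagy median at 0.78.

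The G2/M list held the largest group of falling genes. All 51 measured members fell, also when adjusted over the list alone, with a median fall of 10.7-fold, or 10.0-fold with the 6 members undetected in treated cells at their bounds (camera adjusted p = 2.53e-36; adjusted p = 0.0674 with an estimated correlation). The size depended on the processing: the median log2 fold change was -3.42 as reported, -2.15 without background correction and -1.88 in the authors' values, whose processing is not given in full. There CCNB2 fell 6.94-fold, BIRC5 6.01-fold and CDC20 by 3.87 on the log2 scale. CDC20, the activator of the anaphase-promoting complex, went from 11.83 ± 0.06 (SD, n = 2) to 7.07 ± 0.25 (SD, n = 3), a 27.0-fold fall. CCNB2, a mitotic cyclin, fell 24.6-fold, BIRC5, the chromosomal passenger protein survivin, fell 21.5-fold, and UBE2C fell from 11.59 to 6.39. A second, dimmer probe of UBE2C and of BIRC5 was undetected on the treated arrays and at least 1.56-fold and 2.15-fold lower. Of 37 measured S-phase genes, 36 fell and none rose, also when adjusted over the list alone, with a median log2 fold change of -1.99, or -1.37 in the authors' values (camera adjusted p = 5.35e-23; adjusted p = 0.0674 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell 15.1-fold, and DTL, an adaptor for replication-coupled ubiquitination, fell 9.22-fold (6.17-fold and 2.63-fold in the authors' values). CDC45, part of the replicative helicase, and RRM2, a ribonucleotide reductase subunit, were detected on 1 of 3 treated arrays and fell 21.4-fold and 10.9-fold, or 4.71-fold and 2.54-fold in the authors' values. SLBP, which binds histone mRNA, was the member not called (-0.18), named after its value was seen.

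Genes of biosynthesis and of stress responses fell by smaller medians. Of 32 measured ATF4 and integrated stress response genes, 24 fell and 2 rose (25 and 2 adjusted over the list alone), with a median log2 fold change of -1.05, or -1.04 with 3 members at their bounds (camera adjusted p = 2.88e-09; adjusted p = 0.0736 with an estimated correlation). The amino acid transporter SLC7A5 was undetected on the treated arrays and at least 5.73-fold lower (2.01-fold in the authors' values), the pseudokinase TRIB3 fell 4.82-fold, the glutamine transporter SLC1A5 fell 4.19-fold (2.56-fold there), and MTHFD2, a mitochondrial folate enzyme, fell 3.01-fold. The transporter SLC38A2 and the phosphatase subunit PPP1R15A, named after their values were seen, rose by 0.79 and 0.95 (PPP1R15A by 0.34 in the authors' values), but SLC38A2 lost its call without DMSO replicate 1 (0.0698) and PPP1R15A without DMSO replicate 3 (0.0725), the highest adjusted p-values of their alternatives. Of 26 MYC and ribosome biogenesis genes, 18 fell and none rose (20 lower adjusted over the list alone; camera adjusted p = 6.07e-07; adjusted p = 0.0674 with an estimated correlation), among them NOP16 by 2.84-fold, DKC1, a pseudouridine synthase, by 2.21-fold and FBL, the methyltransferase fibrillarin, by 2.13-fold. Of 23 endoplasmic reticulum chaperone and folding genes, 11 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.000849; adjusted p = 0.100 with an estimated correlation). SDF2L1 fell 2.98-fold, MANF 2.42-fold, PDIA6 2.14-fold and DNAJB11 1.89-fold. HSPA5, the main chaperone of that compartment, named after its value was seen, was not called (0.44, adjusted p = 0.0817), but passed the threshold, upwards, with detection on all arrays and without K-11706 replicate 2 (adjusted p 0.0449 to 0.332 over its alternatives). Of 29 proteasome subunits 4 fell (PSMD14, PSMB5, PSMB2 and PSMA5), 1 of them adjusted over the list alone (camera adjusted p = 0.0383; adjusted p = 0.378 with an estimated correlation). PSMD14, a deubiquitinase of the proteasome lid, fell 1.71-fold. With the replicate block the proteasome list and PSMB5, PSMB2 and PSMA5 lost their calls. The list's call was lost without DMSO replicate 1 (adjusted p = 0.0970), K-11706 replicate 2 (0.0678) or K-11706 replicate 3 (0.0592), over a range of 0.00942 to 0.0970 without the estimated correlation, and each of the 4 subunits lost its call without DMSO replicate 1.

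Lysosome and autophagy genes were the only list called higher by camera with the preset correlation, except that with no filter the neuroendocrine markers were called too. Of 38 measured members 24 rose and 1 fell (26 and 2 adjusted over the list alone), with a median log2 fold change of 0.78 (camera adjusted p = 6.10e-06; adjusted p = 0.0674 with an estimated correlation). The cathepsins CTSF and CTSD, lysosomal proteases, rose 3.15-fold and 2.27-fold, and NPC2, a lysosomal cholesterol carrier, rose 2.14-fold. GLA, the lysosomal alpha-galactosidase, fell 2.14-fold.

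With 1 probe per gene, the brightest, the largest rise among genes detected on all arrays was that of SAT1, the acetyltransferase that starts polyamine breakdown, which went from 10.06 ± 0.04 (SD, n = 2) to 13.34 ± 0.05 (SD, n = 3), a 9.74-fold rise (log2 fold change 3.28, SE 0.12, adjusted p = 1.39e-05). The histone gene H2BC21 rose 6.33-fold, QSOX1, a disulfide-forming oxidase, 5.48-fold, HELZ2, a nuclear receptor coactivator, 5.30-fold, and ID1, an inhibitor of helix-loop-helix transcription factors, 5.27-fold. A second probe of QSOX1, detected on 1 of 2 DMSO arrays, rose further, by 3.46 on the log2 scale, and a second probe of ID1 rose 3.26-fold. EFR3B rose 5.19-fold, the sterol reductase TM7SF2 5.14-fold, the RNA endonuclease ZC3H12A 5.03-fold, EVA1B 5.01-fold, ENPP5 4.85-fold and the vault protein MVP 4.76-fold. In the authors' values TM7SF2 rose 5.40-fold, but EFR3B 2.01-fold, ZC3H12A 3.17-fold, EVA1B 2.29-fold, ENPP5 2.96-fold and MVP 2.23-fold, so the order of these rises depended on the processing. IQCN, HRC and SH3GL2 were detected only on treated arrays and were at least 9.71-fold, 5.84-fold and 4.43-fold higher, bounds that hold only for the processing used: in the authors' values their folds were 2.62, 1.92 and 1.65. The other large falls were of mitotic genes: HMMR fell 34.7-fold, the kinesin KIF20A 21.8-fold, the kinase NEK2 21.4-fold and DLGAP5 19.8-fold, against 10.4-fold, 5.79-fold, 8.63-fold and 5.38-fold in the authors' values. FAM72D and the microtubule regulator PSRC1 were undetected on the treated arrays and at least 11.4-fold and 10.4-fold lower, against 2.94-fold and 2.62-fold in the authors' values.

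**Figure D2:**
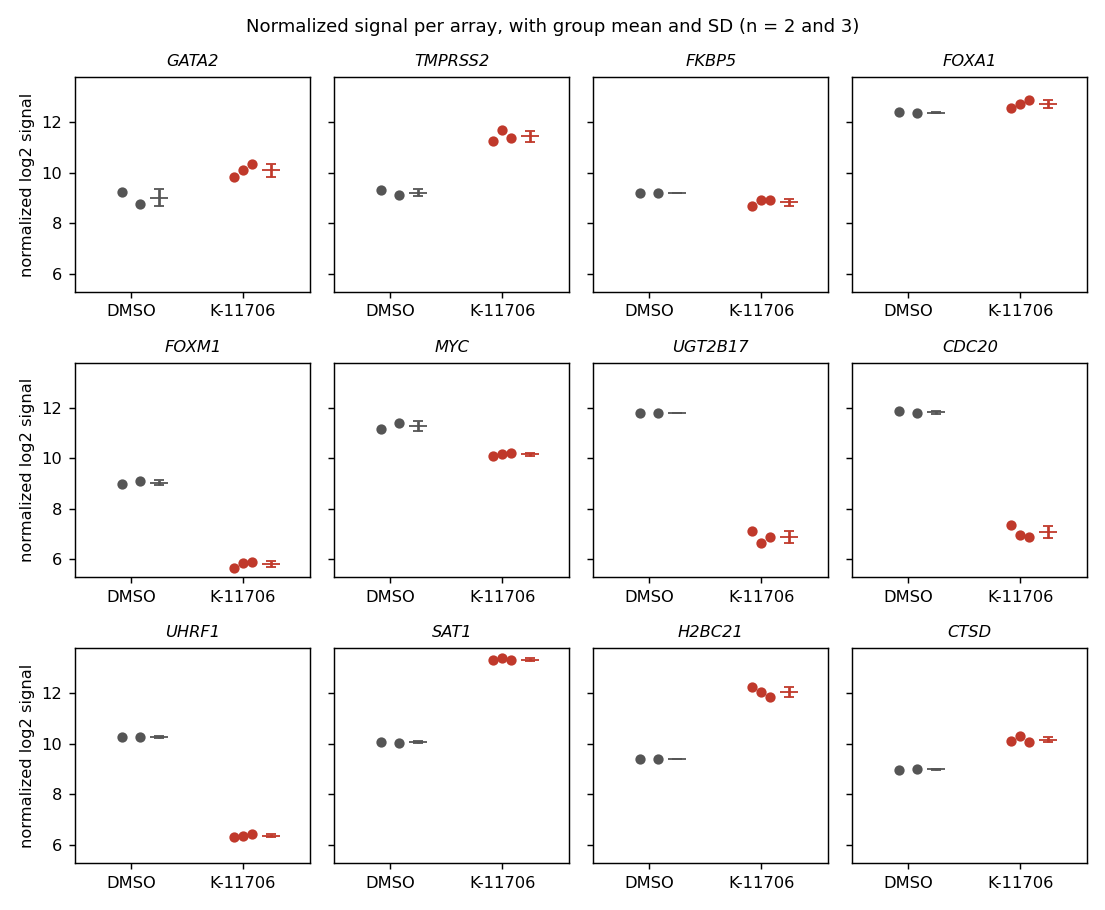
Points are the normalized log2 signal (vertical axis) of 12 genes on each of 2 DMSO arrays (grey) and 3 K-11706 arrays (red), and the bars beside them are the group mean and SD. SAT1 reads 10.06 in DMSO and 13.34 with K-11706, CDC20 reads 11.83 and 7.07, and the GATA2 arrays lie between 8.78 and 10.34.

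Camera made no call for the remaining lists, and their small groups of called members are named here after their values were seen. Fry, which tests a list on its own, called some of these lists. In the next sentences the brackets hold the counts higher and lower adjusted over the list alone and the camera adjusted p. Glucocorticoid receptor targets had 7 higher and 2 lower of 13 (8 and 3; 0.179), the lower ones being TSC22D3 and CEBPD. Cholesterol synthesis and uptake genes had 6 higher and 3 lower of 21 (6 and 3; 0.565), with EBP, ACAT2 and FADS1 lower. Fatty acid synthesis genes had 6 higher and 3 lower of 15 (7 and 3; 0.565), and the elongase ELOVL6 fell by 2.30 on the log2 scale, with THRSP and ME1 also lower. Of 6 measured genes in the list of cholesterol efflux and liver X receptor genes 3 rose (3 and 0; 0.188): MYLIP, LPCAT3 and SREBF1, the last 2.52-fold. That list is not limited to efflux genes. Steroid metabolism genes had 0 higher and 3 lower of 8 (1 and 3; 0.201), namely AKR1C2 (detected on 1 of 3 treated arrays), AKR1C3 and HSD17B6. Heat shock genes had 0 higher and 2 lower of 18 (0 and 1; 0.547), CRYAB and HSPA4. NRF2 targets had 3 higher and 6 lower of 17 (3 and 6; 0.325), the ferritin light chain FTL rising 3.77-fold beside EPHX1 and TXNRD1. Hypoxia and glycolysis genes had 2 higher and 7 lower of 28 (2 and 7; 0.174), HK1 and the mitophagy receptor BNIP3L being higher. p53 targets had 6 higher and 7 lower of 26 (6 and 7; 0.621). Oxidative phosphorylation genes had 2 higher, NDUFA13 and COX6A1, and 3 lower, CYC1, ATP5MC1 and ATP5F1D, of 41 (1 and 2; 0.528), and ribosomal protein genes 0 higher and 8 lower of 54 (0 and 6; 0.0597). Camera called the ribosomal protein list lower under 5 alternatives, among them the authors' values (adjusted p = 0.0176) and the mean of a gene's probes (0.00397), over a range of 0.00397 to 0.342. Interferon-stimulated genes had 5 higher and 6 lower of 23 (5 and 7; 0.365), IRF1, IRF9, IFI35, IFI6 and IRF7 being higher, and of 8 NF-kB and cytokine genes TNFAIP2 alone was called, undetected on the treated arrays and at least 1.15-fold lower (0 and 1; 0.547). Immediate early genes had 2 higher and 6 lower of 17 (2 and 6; 0.565), among them JUN, a subunit of AP-1, 3.58-fold higher and the phosphatase DUSP1 2.57-fold higher. Apoptosis regulators had 4 higher, BIRC2, BCL2L1, MCL1 and CASP9, and 6 lower of 21 (5 and 6; 0.547). The median and the mean differed in sign for cholesterol (-0.04 and 0.18, the test upwards), heat shock (0.02 and -0.07, downwards), p53 (-0.02 and 0.02, downwards), immediate early (0.02 and -0.04, downwards) and apoptosis genes (0.0035 and -0.30, downwards). Leaving out at least 1 of the 5 arrays, always with DMSO replicate 1 or 3 among them, ended the calls of CEBPD, ACAT2, FADS1, MYLIP, AKR1C3, HSD17B6, HSPA4, EPHX1, TXNRD1, HK1, NDUFA13, COX6A1, ATP5F1D, IRF1, IRF9, IFI35, TNFAIP2, BIRC2, BCL2L1 and MCL1, which were lost under 1 to 7 alternatives each and whose highest adjusted p over the alternatives lay between 0.0633 (FADS1) and 0.321 (HSPA4).

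Markers of other cell types were few. Of 6 measured neuroendocrine markers 4 rose (4 adjusted over the list alone) and camera made no call (adjusted p = 0.0597), except with no filter (0.0380, over a range of 0.0380 to 0.330 by camera): TUBB3, ENO2, INSM1 and SYP, named after their values were seen, rose by 1.57, 1.31, 0.72 and 0.68 on the log2 scale (TUBB3 by 0.96 in the authors' values), INSM1 and SYP losing their calls under 6 alternatives each, with the highest adjusted p-values without DMSO replicate 3 (0.130 and 0.215); SYP was detected on 1 of 2 DMSO arrays. Of 8 luminal prostate markers 2 rose (KRT8 by 1.41 and CDH1 by 0.40) and KRT19 was called lower, undetected on the treated arrays and at least 1.18-fold lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.739, test downwards). Their median of -0.31, or -0.26 with 1 member at its bound, and their mean of 0.0093 differed in sign, and CDH1 (0.179 without DMSO replicate 1) and KRT19 (0.188 without DMSO replicate 3) lost their calls under 6 and 8 alternatives, with these the highest adjusted p-values. Of 6 fibroblast markers TAGLN alone rose, by 1.05 (0.33 in the authors' values), also when adjusted over the list alone (camera adjusted p = 0.736, test downwards; median -0.24 and mean 0.02). Of 5 mesenchymal genes limma called none, also when adjusted over the list alone, with 1 at an unadjusted p-value under 0.05 (camera adjusted p = 0.934). Of the blood cell markers 3 were measured and CD68, named after its value was seen, alone rose, by 0.57, also when adjusted over the list alone, and its call was lost under 7 alternatives, with the highest adjusted p without DMSO replicate 1 (0.208). No basal or endothelial marker had a named probe that was detected on enough arrays to be tested.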

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

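Of the tests in this part, those of the gene families were chosen after the data were seen. Probe counts higher and lower stayed within 1.5 times of 3537 and 3210 under the other settings of background, normalization, filter and variance, and moved to 1708 and 1792 with a minimum fold of 1.2. Leaving out single arrays gave 1488 to 3408 probes higher and 1642 to 3092 lower, and 994 to 2173 genes higher and 1035 to 1834 lower; with DMSO replicate 1 or 3 out, 1 DMSO array is left, assumed to vary like the treated arrays. No probe called as reported was called the other way under any of the 15 alternatives that count probes. With no array left out, 8 of 30 lists were called lower and 1 higher by camera. Fry, which tests a list on its own, called 16 lower and 5 higher. These higher ones were the androgen-induced, glucocorticoid receptor, cholesterol efflux and liver X receptor, lysosome and neuroendocrine lists. Camera with an estimated correlation called 0 and 0 (8 lists at an unadjusted p under 0.05). With no filter camera called 2 higher, the lysosome list and the neuroendocrine markers. Leaving out single arrays left 1 list higher and 7 to 9 lower. Apart from the estimated correlation, 8 of the 9 called lists kept their call under every alternative run (highest adjusted p 0.00325) and the proteasome list lost it under 4; the ribosomal protein list gained a camera call, lower, under 5. GATA2 ranged from 0.85 to 1.31 with single arrays left out and lost its call without DMSO replicate 3. FKBP5 passed the threshold at -0.30 without background correction, -0.33 with an offset of 50, -0.28 in the authors' values and -0.35 with an intensity trend, and FOXA1 at 0.34, 0.35, 0.36 and 0.35; the cause was not tested.

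Directions turned only for results not called as reported, and the cause was not tested: interferon-stimulated genes (adjusted p = 0.642) and apoptosis regulators (0.916) with detection on all arrays; p53 targets (0.135), luminal markers (0.469) and fibroblast markers (0.478) by fry; mesenchymal genes without DMSO replicate 3 (0.925) or K-11706 replicate 1 (0.967; all single arrays left out, 0.816 to 0.967); MYC and MXD genes in the authors' values (0.996), with detection on all arrays (0.982) and without DMSO replicate 1, K-11706 replicate 1 or K-11706 replicate 3 (0.974 to 0.992; all single arrays left out, 0.783 to 0.992); E2F1 and CCND1 without DMSO replicate 1 (0.19 and 0.013; all single arrays left out, -0.65 to 0.19 and -0.14 to 0.013); and PAOX without DMSO replicate 3 (-0.054; all single arrays left out, -0.054 to 0.24). Of 139 called genes named in the text 96 kept their call under every alternative run. The groups share replicate numbers 1 and 3, which the labels do not call pairs, and the deviations from the group means correlated across probes at 0.0325 and 0.0418. DMSO has no replicate 2, so under the replicate block K-11706 replicate 2 adds nothing to the fitted difference, and fewer residual degrees of freedom remain. Lost calls can therefore come from this loss as well as from pairing. With the replicate block 2684 probes rose and 2523 fell, and 4890 of the 6747 called probes kept their call. Under it 1 of 30 lists, the proteasome, and 20 of the named genes lost their calls. A slide block was not run, since no slide is named. Genes undetected in 1 group have only bounds. In the authors' values 44 of the 139 genes, 15 of them higher and 29 lower, had folds over 1.5 times smaller, against 36 without background correction, 21 with an offset of 50 and 0 with scaling to the 75th percentile; the cause in the authors' values was not tested.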

Other observations

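The gene families and tests below were chosen after the data were seen, apart from the count over other splits of the arrays. Of 4 measured genes of polyamine synthesis, ODC1, AMD1 and SRM fell by 0.60, 0.83 and 1.03 on the log2 scale (camera adjusted p over 6 families = 0.0153; adjusted p = 0.147 with an estimated correlation). Of 4 genes of polyamine breakdown, SAT1, which prompted the family, SAT2 and SMOX rose, SAT2 by 0.90 and SMOX by 0.85 (0.25 in the authors' values), and PAOX (0.09) was not called. Camera called the family with SAT1 (adjusted p = 0.0211, or 0.302 with an estimated correlation) and not without it (0.174). The median log2 fold change was 0.87 with SAT1 and 0.85, the value of SMOX, over the 3 genes left. A median of so few genes reacts little to 1 member, so whether SAT1 alone carried the change is not decided. Single genes lost their calls with an array left out, SMOX without DMSO replicate 3 (0.223, and under 5 other alternatives), ODC1 without DMSO replicate 3 (0.0807, and without DMSO replicate 1) and SRM without DMSO replicate 1 (0.0515), the highest adjusted p-values of their alternatives. The 3 measured ID genes, inhibitors of helix-loop-helix factors, all rose, ID3 by 2.10 and ID2 by 0.99 (adjusted p = 0.00590; adjusted p = 0.147 with an estimated correlation), and without ID1, which prompted the family, the adjusted p was 0.0211 (adjusted p = 0.181 with an estimated correlation). In the MYC and MXD family MXD1 and MXD4, which oppose MYC at shared sites, rose by 1.87 (MXD1 by 0.62 in the authors' values) and 1.27, while MYC fell by 1.12 and MXD3, detected on 1 of 3 treated arrays, fell by 1.82 (-0.51 in the authors' values), and camera did not call the family (adjusted p = 0.926), whose direction turned under 5 alternatives. Of 8 FOXO and arrestin-domain genes 4 rose, TXNIP by 1.88, ARRDC4 by 1.65 (0.65 in the authors' values), FOXO3 by 1.11 and FOXO1 by 0.41 (adjusted p = 0.0168; adjusted p = 0.302 with an estimated correlation); without TXNIP, which prompted the family, 3 of 7 were higher and none lower, and the median moved from 0.61 to 0.58 while the adjusted p rose to 0.0541, and FOXO1 lost its call under 10 of 15 alternatives, among them each array left out in turn (highest adjusted p 0.175, without DMSO replicate 3).

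Cell cycle genes were lower in the treated arrays. Dimmer arrays are argued against by the number of detected probes, which differed by -0.300% in the mean of the treated arrays. That number does not measure RNA integrity, so poorer RNA stays open. Background correction and normalization are argued against by the G2/M median, which was -1.88 at its nearest to 0 over the processing alternatives. Separate growth or hybridisation of the 2 groups cannot be told apart from the treatment, since the labels name 0 batches that hold both, and the protocol text of the DMSO samples describes another compound. A response of the cells to K-11706 stays among the open explanations, untested.

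The 10 splits of the 5 arrays into 2 and 3 are too few for a share under 0.05: with limma the real split called 6747 probes, the highest of the others 0, and 1 of the 10, the real one, reached that count.

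Signals of histone genes rose as a family although the S-phase genes fell: 21 of 44 were higher and 5 lower. H2BC21, H2AC6 and H2AJ rose by 2.66, 2.03 and 1.96, and the median log2 fold change was 0.58 (camera adjusted p = 0.000323, or 0.126 with an estimated correlation). Without H2BC21, which prompted the family, the camera adjusted p was 0.000751 (0.147 with an estimated correlation). The family was chosen by gene name and includes variants such as H2AZ1 and MACROH2A2. Which forms of these transcripts the labelling captured was not tested. A single rising transcript read by every histone probe is argued against by the 5 genes that fell, H4C3, H2AX, MACROH2A2, H2AZ1 and H2BC11, although H2BC11 lost its call under 4 alternatives (highest adjusted p 0.117, without DMSO replicate 1) and sharing among the risers stays open. Of 15 histone genes with a mean DMSO log2 signal over 9, 7 rose and 4 fell. Signals near background are argued against for these 7 risers. H2AC18 went from 10.71 to 12.63 and H3-5, the smallest of these rises, from 10.16 to 11.13, where the lowest detected signals were 4.95 to 4.98. Under a signal of 9 they are also argued against for H2AC6 (8.46 to 10.50), H4C8 (8.24 to 10.09) and H2BC5 (8.03 to 9.67). H2BC11, also under 9, fell (6.21 to 5.63). For the family as a whole signals near background stay open: the median change of the 15 genes, 0.13 over members that moved both ways, does not decide. A response of the cells to K-11706 stays among the open explanations, untested.

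The androgen-repressed list fell, led by the 5 UGT2B genes, whose probes may read each other's transcripts. That this sharing made the whole list fall is argued against by the list without them (adjusted p = 0.0332; adjusted p = 0.278 with an estimated correlation). For the UGT2B genes themselves, sharing cannot be told apart from 5 separate falls: their log2 changes spanned 0.943, neither equal nor clearly apart. A response of the cells to K-11706 stays among the open explanations, untested.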
